A study of Mus musculus with 8 samples.

How the data were processed

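Whole mouse embryos of the C57BL/6 background were collected at embryonic day E6.75 as 4 Control and 4 Tet1/2/3 triple-knockout (TKO) embryos. Each was lysed singly and its RNA was turned into cDNA with a SMARTer low-input kit, then into Nextera XT libraries for an Illumina HiSeq instrument, per the labels' protocols. The labels describe single embryos, so the p-values cover the spread between these 8 embryos. The labels name no litter, sex, date or batch. Groups and replicate numbers were taken from the sample labels.

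The deposited table gives RPKM (reads per kilobase of gene model and per 1000000 mapped reads), computed by the authors, as 1 value per gene symbol and embryo for 21182 symbols. The unit is taken from the name of the deposited table and from its non-integer values. HTSeq, with no version, and genome build mm9 are named per the submitters' processing notes. The aligner, the gene annotation and its lengths, the read total used as denominator and the use of strand are not given in the sources used here. Reads of near-identical genes could therefore have been split in ways not known here, and reads of a gene and its antisense partner cannot be told apart. The reference used here has another build (GRCm38), so no coordinates are given, and it served only for transcript lengths, GC content and older gene symbols. A transcript length in GENCODE release M21 was found for 98.6% of the symbols, 19036 by their current symbol and 1839 by an older one from RefSeq synonyms. Of the symbols, 25 read as dates, as spreadsheet software makes them, and the genes behind them are not named here. All 8 columns matched a sample, no symbol occurred more than once, and no pair of columns shared more than 0.07% of its values above 1 RPKM.

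Depth was estimated from the smallest values, because an RPKM value times the gene length is a whole number of reads divided by the read total. For genes with 1 annotated transcript and an RPKM between 0.03 and 1, the read total was placed where most values came out at 1 to 3 reads, within 2%. At that total, 46.0% to 54.7% of the low values lay at 1 to 10 whole reads, against 7.2% to 8.3% at totals drawn at random. The other low values lay above 10 reads or did not come out whole, which were not told apart. The transcript lengths used here also come from another build than the gene models. Reads were therefore not recovered and no count test was run. The estimates are 16.52, 14.95, 12.48 and 14.37 M reads (M for 1000000) for Control replicates 1 to 4, and 9.91, 14.18, 19.08 and 11.75 M reads for TKO replicates 1 to 4.

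Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with the variance trend of eBayes, on genes with an RPKM of at least 1 in at least 4 of the 8 embryos. No block or covariate was used. P-values are two-sided, were adjusted by Benjamini-Hochberg over all tested genes, and were held against 0.05. A log2 difference is that of the TKO-labelled minus the Control mean on the log2(RPKM + 1) scale, which understates the change of low genes. Means and SDs are in RPKM over 4 embryos. Values of single genes were also compared by an exact two-sided permutation over all 70 assignments of the 8 embryos, for which 0.0286 is the smallest possible p.

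Gene lists were written down before the data were examined, as were the model, the filter, the rule for named genes and the alternatives, except where an alternative is said to be added later. The 36 lists cover the TET and DNA methylation machinery, embryonic and extraembryonic tissues, maternal decidua and blood, germline and imprinted genes, signalling pathways, stress, metabolism, the cell cycle and Y-linked genes. Of these, 31 had at least 5 tested members and were tested with camera from limma, which compares a list with the other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 31 lists. The mean log2 level of each list per embryo gave its difference and SE. Alternatives were camera with a correlation estimated from these embryos, fry, and an exact permutation of each list's mean. Unless an estimated correlation is named, a call by camera used the preset correlation, in the other alternatives too. The Y-linked list was not tested with camera.

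The spread between embryos was compared as the median over genes of the log2 ratio of SDs, TKO-labelled over Control, with an exact permutation of group-centred values.

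Genes are named by this rule: Tet1, Tet2 and Tet3; Nodal, Lefty1, Lefty2, T, Mixl1 and Eomes; the genes past the threshold with the largest differences or, with fewer than 5 in a direction, the 8 with the smallest unadjusted p, a mean of at least 5 RPKM and no overlap between groups, leaving out predicted genes; and from each list the members past the threshold or the 2 with the smallest unadjusted p. Prl8a2, the decidual prolactin of the decidua list, Xist, the Y-linked genes and the genes called without 1 embryo were named after their values were seen.

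The alternatives were other pseudocounts, low-value filters and scalings, weights per embryo, no variance trend, a replicate block, tissue and Y-linked lists as covariates, stricter thresholds, and leaving out each embryo in turn. Decidua and parietal endoderm covariates, a correction for transcript length and GC content (a lowess trend per embryo), the exact permutation of list means and the counts at unadjusted p or without overlap between groups were added after the data were seen. A value that was past no threshold and whose sign changed by less than its own SE was counted as keeping its direction. Replicate numbers were treated as names, since the labels do not say that they mark a shared litter or batch.

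The model was tested on simulated data for 10451 genes in 4 against 4 embryos with the measured gene-wise spread. It recovered 22% of 50 genes shifted by a log2 of 0.5, 94% of those shifted by 1, 98% of those shifted by 2 and 72% of those shifted by -1, with 7 false among 150 calls. A list shifted by 1 was found by camera among genes drawn independently, and 0 other lists were called. Lists that share a member with the shifted list were left out of that count. Results of 4 single genes are not reported here, though these genes stay in every test and count. Figures were drawn with matplotlib 3.10.9 from the tabulated values.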

Results

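Gene expression was measured by RNA sequencing of single whole mouse embryos at embryonic day E6.75, when the epiblast begins to form the primitive streak. The labels give 4 Control embryos and 4 triple-knockout (TKO) embryos, the latter without the methylcytosine dioxygenases Tet1, Tet2 and Tet3. They make up 1 comparison, which asks how gene expression in the early embryo depends on the TET enzymes. Estimated depth averaged 14.58 ± 1.67 M reads (M for 1000000) in Control and 13.73 ± 3.97 M reads in TKO-labelled embryos (SD, n = 4 each), and was lowest, at 9.91 M, in TKO replicate 1. Of the 21182 genes, 2186 to 4466 were listed at 0 in a Control embryo and 3227 to 4942 in a TKO-labelled embryo. Among TKO-labelled embryos this number fell as depth rose. Among Control embryos it was highest at the highest depth (replicate 1, 16.52 M) and lowest at the lowest (replicate 3, 12.48 M), so depth alone does not set it.

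The targeted genes were compared first, because they check the labels. Tet1, a TET enzyme of the epiblast and germline, averaged 5.24 ± 0.37 RPKM in Control and 11.4 ± 2.82 RPKM in TKO-labelled embryos (SD, n = 4 each). Each TKO-labelled embryo, at 9.21 to 15.3 RPKM, lay above each Control embryo, at 4.93 to 5.76 RPKM. Its log2 difference was 0.97 (95% confidence interval 0.63 to 1.31). The limma p was 6.88e-05 before and 0.103 after Benjamini-Hochberg adjustment over 10451 genes, and 5.51e-04 when adjusted over the list alone. Tet2 averaged 0.725 ± 0.189 RPKM in Control and 0.784 ± 0.172 RPKM in TKO-labelled embryos, below the filter, with an exact permutation p of 0.657. Tet3, the TET enzyme of the oocyte and zygote, averaged 1.85 ± 0.16 RPKM in Control and 1.38 ± 0.25 RPKM in TKO-labelled embryos, a log2 difference of -0.26 (95% confidence interval -0.54 to 0.01, limma adjusted p = 0.297). For both Tet1 and Tet3 the 4 values of one group did not overlap those of the other, and the exact permutation p of each was 0.0286, the smallest possible. The Tet1 level thus goes against a loss of its transcript, and the embryos are called TKO-labelled throughout, since each direction below rests on the label. A single value per gene cannot show whether targeted exons were missing, because reads from the rest of a transcript still count, so these values do not check a deletion of exons. Without TKO replicate 1 the log2 difference of Tet1 was 0.83 (limma adjusted p = 0.0306), while over all alternatives its adjusted p ranged from 0.0306 to 0.320.

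**Figure D1:**
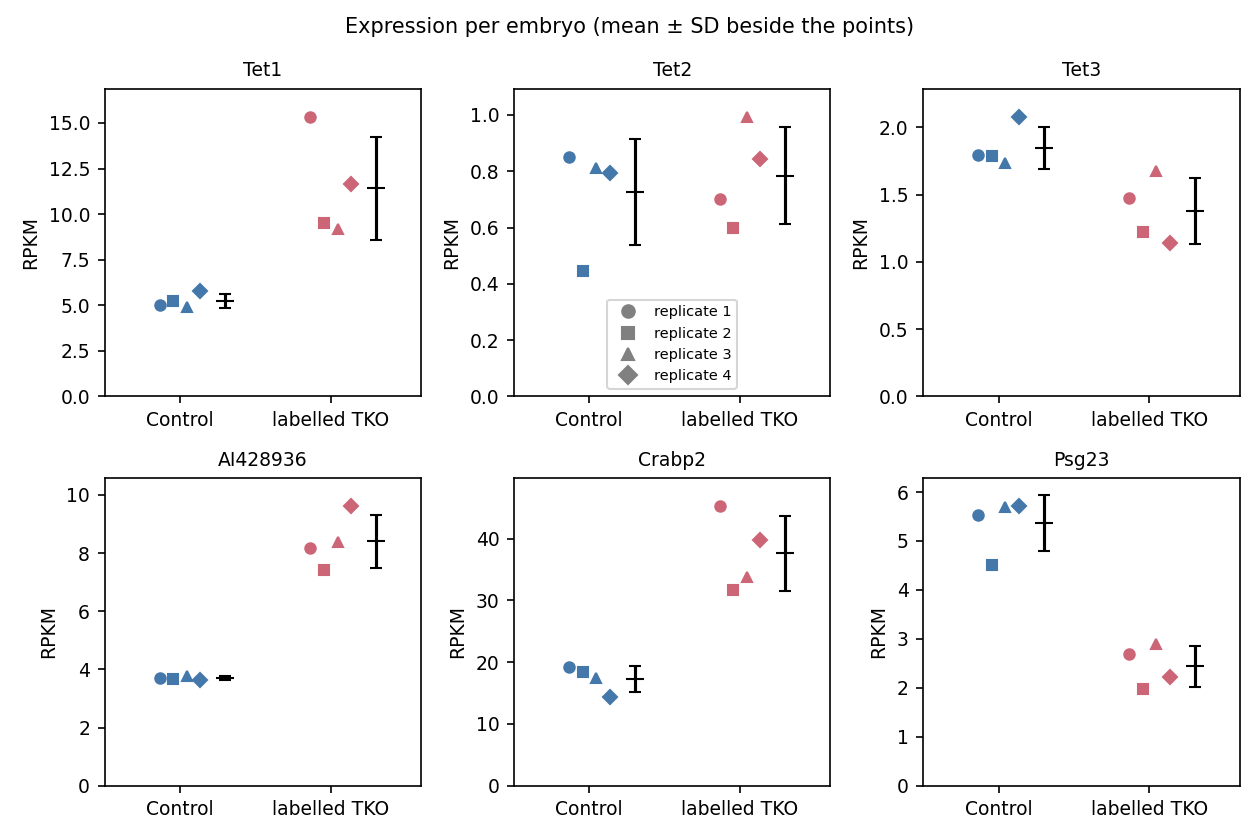
RPKM of 6 genes in each embryo (vertical axes from 0), with Control embryos in blue, TKO-labelled embryos in red, a marker shape per replicate number, and the mean ± SD of 4 embryos as a bar beside the points. For Tet1, Tet3, AI428936, Crabp2 and Psg23 the 4 values of one group do not overlap those of the other, while those of Tet2 do; of the 6 genes only AI428936 passed the adjusted threshold (limma adjusted p = 0.0248).

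Across the genome 1 gene rose past the threshold and 0 fell. AI428936, an older symbol of Syne4, which encodes the outer nuclear membrane protein nesprin-4, rose from 3.70 ± 0.06 to 8.41 ± 0.90 RPKM (log2 difference 1.00, SE 0.11, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0248) and was higher in all 4 TKO-labelled embryos. The call ended in 6 of the 8 fits that left out 1 embryo, where its adjusted p ranged from 0.0170 to 0.174. At an unadjusted limma p under 0.05 there were 1824 genes, 1448 with higher and 376 with lower values in TKO-labelled embryos, against 523 by chance. The 4 values of each group did not overlap in 983 genes (789 higher, 194 lower), or 9.41% of those tested, against 2.86%, or 299 genes, by chance. The split toward higher values depended on the scale: after median-ratio scaling, which moved the median log2 difference of all genes from 0.09 to 0.01, the 1523 genes at that p were 804 higher and 719 lower, 52.8% against 79.4% higher.

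Of the genes with the smallest p that missed the threshold, 7 with higher and 7 with lower values in TKO-labelled embryos are described here, Tet1 being 1 of the 7. Crabp2, which carries retinoic acid inside cells, averaged 17.3 ± 2.09 RPKM in Control and 37.6 ± 6.14 RPKM in TKO-labelled embryos (log2 difference 1.07, limma adjusted p = 0.0576). Slc7a7, a subunit of a cationic amino acid transporter, averaged 17.0 and 31.5 RPKM (0.85, limma adjusted p = 0.0897). Bin1, a protein that bends membranes, averaged 4.34 and 9.34 RPKM (0.94, limma adjusted p = 0.0813). The log2 differences of Asah1, the lysosomal acid ceramidase, Otub1, a deubiquitinating enzyme, and Txndc12, a thioredoxin-like protein of the endoplasmic reticulum, were 0.75, 0.69 and 0.97, with limma adjusted p-values of 0.112, 0.112 and 0.120. With lower values stood Psg23, a pregnancy-specific glycoprotein of the trophoblast, at 5.36 ± 0.57 RPKM in Control and 2.44 ± 0.42 RPKM in TKO-labelled embryos (log2 difference -0.89, limma adjusted p = 0.0813). Psg23 has close paralogs, among which reads can be split. Cpne8, a calcium-dependent phospholipid-binding protein, averaged 20.4 and 8.15 RPKM (-1.22, limma adjusted p = 0.128). The other genes of this group were the protease gene Fam111a (-0.65), the complex I subunit gene Ndufv3 (-0.60), Bola2, which takes part in iron-sulfur protein assembly (-0.67), and the troponin gene Tnnt1 (-0.61), with limma adjusted p-values of 0.120 to 0.132. The microRNA precursor locus Mir363 (log2 difference -1.04, limma adjusted p = 0.112) collects reads of its host transcript and gives no level of the mature microRNA. Without TKO replicate 1, 33 genes rose and 7 fell by limma, among them Crabp2 (log2 difference 0.98, adjusted p = 0.0239) and Psg23 (-0.92, adjusted p = 0.0325).

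Genes of the Nodal pathway, which patterns the epiblast and induces the primitive streak, held 0 genes past the threshold over all genes. Nodal averaged 8.82 ± 2.95 RPKM in Control and 9.59 ± 1.21 RPKM in TKO-labelled embryos (log2 difference 0.15, 95% confidence interval -0.29 to 0.60, limma adjusted p = 0.720). Its secreted inhibitor Lefty1 averaged 5.38 ± 3.15 and 4.95 ± 0.76 RPKM (0.03, interval -0.65 to 0.71, limma adjusted p = 0.968). Lefty2, the other, averaged 2.54 ± 0.89 and 2.40 ± 2.40 RPKM (-0.25, interval -1.07 to 0.58, limma adjusted p = 0.757). Without Control replicate 1 the log2 difference of Lefty1 was -0.28. That of Lefty2 was -0.67 without TKO replicate 2 and 0.02 without TKO replicate 1. The intervals leave open a log2 difference of over 0.5 either way for both Lefty genes. Of 19 tested members of the Nodal list 13 had positive differences, with a list mean of 0.22 (SE 0.07). The camera adjusted p was 0.261 and the exact permutation p 0.0286, or 0.295 adjusted over 31 lists. Adjusted over the list alone, 2 members passed, among them Gdf3. Gdf3, a TGF-beta family ligand related to Nodal, averaged 1.54 ± 0.27 RPKM in Control and 6.54 ± 4.30 RPKM in TKO-labelled embryos (log2 difference 1.40, limma p adjusted over the list alone 0.0274). Over all genes 0 members passed, with a limma adjusted p of 0.145 for Gdf3.

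Among primitive streak genes, 1 TKO-labelled embryo stood far above the others. The T-box gene T, or Brachyury, averaged 4.20 ± 2.14 RPKM in Control and 12.9 ± 14.3 RPKM in TKO-labelled embryos, where replicate 2 reached 34.0 RPKM (log2 difference 0.99, limma adjusted p = 0.386, and 0.37 without that embryo). The homeobox gene Mixl1 averaged 7.55 ± 1.48 and 20.5 ± 18.6 RPKM, with 48.3 RPKM in the same embryo (1.03, limma adjusted p = 0.239, and 0.53 without it). All 4 TKO-labelled values of Mixl1 lay above the Control values, with an exact permutation p of 0.0286. Eomes, expressed in the streak and in extraembryonic ectoderm, averaged 51.7 ± 10.2 and 53.03 ± 12.4 RPKM (0.03, limma adjusted p = 0.951). The streak list had a mean of 0.45 (SE 0.26) with 9 of 10 members positive and a camera adjusted p of 0.239. Without TKO replicate 2 the list mean was 0.21, and camera called the list only with no filter on low values or without TKO replicate 4 (adjusted p 0.0234 to 0.950 over all alternatives). It had 0 members past the threshold adjusted over the list alone or over all genes. Its other leading member Lhx1, a homeobox gene of the anterior streak, axial mesendoderm and anterior visceral endoderm, averaged 2.57 ± 0.40 and 4.81 ± 2.05 RPKM (0.65, limma adjusted p = 0.182).

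The mesoderm list (mean 0.31, SE 0.12, 11 of 15 members positive, camera adjusted p = 0.339) held 4 members past the threshold adjusted over the list alone and 0 over all genes. They included Gata6, at 3.63 ± 0.99 and 10.2 ± 4.08 RPKM (log2 difference 1.20), and Gata4, at 4.96 ± 1.69 and 9.21 ± 1.40 RPKM (0.81), both with a limma p of 0.0149 adjusted over the list alone. Gata6 was at 4.51 RPKM in TKO replicate 1, inside the Control range of 2.64 to 4.99 RPKM, and its log2 difference was 0.35 with the parietal endoderm covariate (limma adjusted p = 0.287, in a range of 0.0170 to 0.374), so it is not told apart here from the parietal endoderm level. These GATA factors also mark primitive endoderm and its derivatives, and Gata6 also stood in the visceral endoderm list. The list of definitive endoderm and axial mesendoderm had a mean of 0.30 (SE 0.11, camera adjusted p = 0.153), with Foxa1 at 1.25 and 1.81 RPKM. Camera called that list higher with no filter on low values, with the visceral endoderm covariate (mean 0.36, adjusted p = 0.0190) and without TKO replicate 4. Its adjusted p ranged from 0.00892 to 0.660 over all alternatives. The list of the anterior visceral endoderm, a source of Nodal and Wnt inhibitors, had a mean of 0.18 (SE 0.14, camera adjusted p = 0.379, mean 0.06 without TKO replicate 1), with the Wnt inhibitor gene Dkk1 at 13.0 and 15.8 RPKM. In these 2 lists 0 members passed the threshold adjusted over the list alone.

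Epiblast genes had a list mean of 0.28 (SE 0.19, 13 of 18 members positive, camera adjusted p = 0.261). Without TKO replicate 1 the mean was 0.15. Camera called the list higher with no filter on low values and with the visceral (mean 0.42, adjusted p = 0.00779) or parietal endoderm covariate (0.58, adjusted p = 0.00340), in a range of 0.00340 to 0.880 over all alternatives. These calls used the preset correlation of 0.01, whereas that estimated from all 8 embryos was 0.355. Pou5f1, which encodes the pluripotency factor Oct4, averaged 15.3 ± 3.96 RPKM in Control and 32.8 ± 18.0 RPKM in TKO-labelled embryos, with 57.3 RPKM in replicate 1 (log2 difference 0.93, limma adjusted p = 0.215). Fgf5, a marker of the postimplantation epiblast, averaged 31.1 ± 6.45 and 41.6 ± 4.62 RPKM (0.43, limma adjusted p = 0.227). The naive pluripotency list had a mean of 0.18 (SE 0.08, camera adjusted p = 0.861), and its 2 leading members had opposite signs. Dppa4 averaged 35.7 ± 7.74 and 67.4 ± 34.1 RPKM, and Klf2 2.47 ± 0.42 and 1.25 ± 0.70 RPKM. The neuroectoderm list had a mean of -0.07 (SE 0.11, camera adjusted p = 0.202), and without TKO replicate 1 one of -0.17, called lower by camera (adjusted p 0.0207 to 0.887 over all alternatives). Irx3 averaged 3.26 and 2.09 RPKM and Nes, the neural progenitor filament nestin, 1.84 and 2.45 RPKM. In these 3 lists 0 members passed the threshold adjusted over the list alone or over all genes.

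Among genes of signalling pathways, camera called 0 lists in the fit of all 8 embryos. The FGF list had a mean of 0.19 (SE 0.10, camera adjusted p = 0.354). Of its 13 members 1 passed the threshold adjusted over the list alone, the ligand gene Fgf10, at 2.29 ± 0.52 RPKM in Control and 3.93 ± 0.50 RPKM in TKO-labelled embryos. Its log2 difference was 0.59 (limma p 0.0245 so adjusted, 0.155 over all genes). The FGF receptor gene Fgfr2 averaged 10.6 ± 1.25 and 7.85 ± 0.89 RPKM (-0.39). The Wnt list had a mean of 0.21 (SE 0.12, camera adjusted p = 0.688), or 0.11 without TKO replicate 2. The BMP list had a mean of -0.02 (SE 0.07, camera adjusted p = 0.261). The BMP target Id2 averaged 239 ± 40.0 and 195 ± 40.8 RPKM, and the signal transducer gene Smad5 5.04 and 5.81 RPKM. The Notch list had a mean of -0.06 (SE 0.08, camera adjusted p = 0.190). The Notch feedback inhibitor gene Nrarp averaged 2.85 ± 0.39 and 2.01 ± 0.39 RPKM, and the ligand gene Dll3 1.17 and 1.62 RPKM. In the list of epithelial-mesenchymal transition (mean 0.23, SE 0.09, camera adjusted p = 0.339) 2 members passed the threshold adjusted over the list alone and 0 over all genes. They were the matrix metalloproteinase gene Mmp2, at 1.88 ± 0.57 and 3.78 ± 0.46 RPKM (0.75, limma p 0.0127 so adjusted), and the transcription factor gene Twist1, at 1.37 ± 0.11 and 2.42 ± 0.66 RPKM (0.51, limma p 0.0395 so adjusted).

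Parietal endoderm genes, which make the thick basement membrane between embryo and trophoblast, had the largest difference between groups of the 31 tested lists. The list mean was 3.07 ± 0.46 in Control and 4.31 ± 0.92 in TKO-labelled embryos on the log2(RPKM + 1) scale (difference 1.24, SE 0.51), and all 13 tested members had positive differences. Nid1, the basement membrane linker nidogen, averaged 6.26 ± 1.94 and 23.6 ± 12.3 RPKM (log2 difference 1.64). Sparc, a matricellular protein, averaged 89.6 ± 25.4 and 209 ± 74.2 RPKM (1.18). Both had a limma p of 0.00876 adjusted over the list alone. Adjusted over the list alone 9 of the 13 members passed, and over all genes 0 did. The list was called higher by camera with Benjamini-Hochberg adjustment (adjusted p = 1.73e-05). The call was lost with an estimated correlation (adjusted p = 0.660), by fry (adjusted p = 0.303) and by exact permutation (p = 0.0857). TKO replicate 1, at 3.02, lay within the Control range of 2.62 to 3.68, and the other 3 TKO-labelled embryos at 4.32 to 5.12. With the parietal endoderm covariate the log2 differences of Gata6, T, Rhox6 and P4ha1, named in other lists, were 0.35, 0.19, 0.38 and 0.10, smaller than without it. These genes do not stand for all. Under the same covariate the mean of the epiblast list grew from 0.28 to 0.58 and that of the germline list from 0.30 to 0.68. Without TKO replicate 1, 8 of the 13 members passed limma's threshold over all genes, led by the laminin genes Lama1 (log2 difference 3.08, adjusted p = 0.0239) and Lamc1 (2.26, adjusted p = 0.0170).

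The other extraembryonic lists overlapped between the groups. The visceral endoderm list had a mean of 0.33 (SE 0.28, 19 of 24 members positive, camera adjusted p = 0.260). Its overlap rests on Control replicate 1, at 6.08, the other Control embryos lying below each TKO-labelled embryo. Without Control replicate 1 the mean was 0.57 and camera called the list higher (adjusted p = 3.02e-05), as it did with no filter on low values, while without Control replicate 3 the mean was 0.16. Over all alternatives the adjusted p ranged from 3.02e-05 to 0.950. Adjusted over the list alone 2 members passed, Gata6 and Rbp4, the retinol-binding protein, at 31.6 ± 14.3 and 59.1 ± 12.6 RPKM (0.95, limma p 0.0391 so adjusted, 0.160 over all genes). Extraembryonic ectoderm had a mean of 0.06 (SE 0.15, camera adjusted p = 0.239) and 0 members past the threshold adjusted over the list alone. Its homeobox gene Rhox6 averaged 16.5 ± 4.96 and 29.9 ± 9.52 RPKM (0.81, limma adjusted p = 0.170). Genes of the ectoplacental cone and trophoblast giant cells had a mean of 0.11 (SE 0.59, camera adjusted p = 0.339), which ranged from -0.34 without TKO replicate 3 to 0.42 without TKO replicate 2. Its transcription factor gene Ascl2 averaged 13.5 ± 2.18 and 10.1 ± 6.56 RPKM and Hand1 3.97 and 3.40 RPKM.

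Maternal decidua genes varied widely between embryos of both groups. Prl8a2, a prolactin of the decidua, ranged from 1.32 to 336 RPKM in Control and from 11.8 to 354 RPKM in TKO-labelled embryos. The list mean was 3.02, 0.92, 4.15 and 3.39 in Control replicates 1 to 4 and 1.69, 1.28, 3.35 and 2.41 in TKO replicates 1 to 4. Of its 13 tested members 12 had negative differences, with a mean of -0.68 (SE 0.83). Camera called the list lower (adjusted p = 4.25e-04), and the call was lost with an estimated correlation (adjusted p = 0.660) and by exact permutation (p = 0.429). It was also lost without Control replicate 3, where the mean was -0.26 (camera adjusted p = 0.0687), while without Control replicate 2 the mean was -1.34. Over all alternatives the adjusted p of the list ranged from 9.41e-12 to 0.660. The transcription factor genes Cebpb, at 9.45 ± 4.78 and 4.15 ± 2.69 RPKM (log2 difference -1.05, limma adjusted p = 0.247), and Hoxa11, at 2.10 ± 1.73 and 0.604 ± 0.752 RPKM, led it. Genes of blood and immune cells were lowest and highest in the same Control embryos. S100a8, a calprotectin subunit of neutrophils, was listed at 0 in Control replicate 2 and reached 26.8 RPKM in Control replicate 3, and its partner S100a9 reached 1.97 RPKM there. These 2 were the only tested members of that list, whose mean difference was -0.77 (SE 0.91). Primitive blood genes, with 3 tested members and a mean of -0.35 (SE 0.20), included Runx1 at 2.07 ± 0.70 and 1.14 ± 0.34 RPKM and Gata1 at 5.62 ± 1.04 and 4.10 ± 2.10 RPKM (limma adjusted p = 0.225 and 0.444). The Hox list had 2 tested members, among them Hoxa10, which was also in the decidua list and reached 12.5 RPKM in Control replicate 3.

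**Figure D2:**
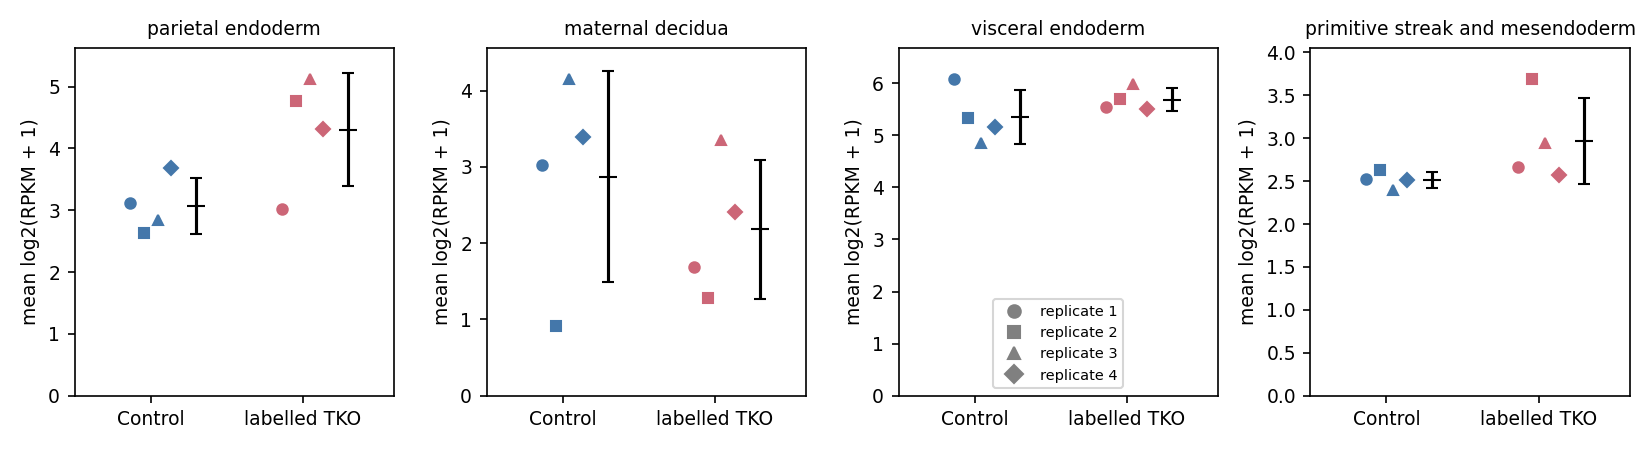
Mean log2(RPKM + 1) of 4 tissue lists in each embryo (vertical axes from 0), with Control embryos in blue, TKO-labelled embryos in red, a marker shape per replicate number, and the mean ± SD of 4 embryos as a bar beside the points. The parietal endoderm level of TKO replicate 1, at 3.02, lies among the Control embryos, the decidua level spans 0.92 to 4.15 within Control alone, and the streak level of TKO replicate 2, at 3.69, stands above the other 7 embryos.

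Germline and imprinted genes, which depend on promoter or imprint methylation, were not called as lists in the fit of all 8 embryos. All 13 tested genes of the germline list had positive differences (mean 0.30, SE 0.22). The camera adjusted p was 0.261 and the exact permutation p 0.229, with 0 members past the threshold adjusted over the list alone. Without TKO replicate 1 the mean was 0.15. Camera called the germline list higher with no filter on low values, with the parietal endoderm covariate and without TKO replicate 2 (mean 0.48), its adjusted p ranging from 0.00124 to 0.901 over all alternatives. These calls used the preset correlation of 0.01, whereas that estimated from all 8 embryos was 0.346. Ddx4, the germ cell RNA helicase Vasa, averaged 6.98 ± 2.27 RPKM in Control and 12.1 ± 3.30 RPKM in TKO-labelled embryos (log2 difference 0.72, limma adjusted p = 0.182). Sohlh2, a germ cell transcription factor, averaged 0.566 ± 0.336 and 2.02 ± 1.32 RPKM. The list of primordial germ cell genes had a mean of 0.11 (SE 0.09, camera adjusted p = 0.649). Dnd1, an RNA-binding protein of germ cells, averaged 4.18 ± 0.29 and 3.31 ± 0.29 RPKM and the receptor gene Kit 0.796 and 1.92 RPKM. Imprinted genes divided evenly, with 14 of 27 members positive and 13 negative (mean -0.04, SE 0.08, camera adjusted p = 0.0971). Camera called the imprinted list lower with the visceral endoderm covariate, without TKO replicate 1 and without TKO replicate 3 (adjusted p 0.0316 to 0.833 over all alternatives). The paternally expressed gene Nnat averaged 4.03 ± 0.25 and 1.87 ± 0.65 RPKM (log2 difference -0.83). It passed the threshold adjusted over the list alone (limma p 0.00863 so adjusted) but not over all genes (0.120). Magel2, also expressed from the paternal allele, averaged 1.91 ± 0.45 and 0.959 ± 0.327 RPKM (-0.57, limma adjusted p = 0.173). The TET and DNA methylation list had a mean of 0.04 (SE 0.12, camera adjusted p = 0.303), with Tet1 the 1 of its 8 tested members past the threshold adjusted over the list alone. Of the 2-cell-like list 1 member was tested, Eif1a, at 87.7 ± 5.93 and 92.0 ± 10.6 RPKM.

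Growth-related lists held 3 of the 4 lower calls. Cytosolic ribosomal protein genes had a mean of -0.19 (SE 0.10), with 63 of 80 members negative and a camera adjusted p of 1.11e-14. The call was lost with an estimated correlation (adjusted p = 0.660) and by exact permutation (p = 0.114). Control replicate 2 was the highest embryo, at a list mean of 10.3. The other Control embryos, at 9.86 to 10.1, overlapped the TKO-labelled embryos, at 9.86 to 9.90. Without Control replicate 2 the mean difference was -0.10 and with quantile normalization -0.08 (camera adjusted p 5.47e-07 and 0.0355), in a range of 9.23e-25 to 0.660 over all alternatives. Rplp2 averaged 1013 ± 185 and 678 ± 95.8 RPKM (log2 difference -0.57) and Rps21 1345 ± 232 and 919 ± 125 RPKM (-0.54), both with a limma adjusted p of 0.160. Nuclear-encoded subunits of respiratory complex I had a mean of -0.10 (SE 0.11), with 23 of 35 negative and a camera adjusted p of 1.36e-04. That call was lost with an estimated correlation (adjusted p = 0.660). Without TKO replicate 1 the mean was -0.04, without Control replicate 1 or 2 -0.05 and without Control replicate 4 -0.16, each still called by camera. Its members went both ways. Ndufv3 averaged 57.0 ± 6.63 and 37.3 ± 3.93 RPKM and passed the threshold adjusted over the list alone (limma p 0.0142 so adjusted). Ndufa10 averaged 79.7 ± 14.6 and 112 ± 14.3 RPKM (0.49, limma adjusted p = 0.173). Replication-dependent histone genes had a mean of -0.17 (SE 0.17), with 13 of 17 negative and a camera adjusted p of 0.00436. With an estimated correlation this call was lost too (adjusted p = 0.660), as it was with no filter on low values (mean -0.05) and the parietal endoderm covariate (0.17). It was also lost with quantile normalization (-0.25) and the length and GC correction (-0.19), where the mean was no smaller. Without Control replicate 1 or 4 the mean was -0.10 or -0.27, and without TKO replicate 1 or 2 it was -0.29 or -0.08, each still called by camera (adjusted p 5.85e-05 to 0.887 over all alternatives). Hist1h4i averaged 14.6 ± 3.13 and 10.8 ± 1.10 RPKM and Hist1h4c 2.26 and 1.25 RPKM. Reads of near-identical histone genes can be split among copies.

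Cell cycle and stress lists were not called by camera in the fit of all 8 embryos. The mitotic cell cycle list had a mean of 0.12 (SE 0.07, 21 of 27 positive, camera adjusted p = 0.303). With no filter on low values camera called it higher (adjusted p = 0.0219, in a range of 0.0219 to 0.901 over all alternatives). The mitotic cyclin gene Ccnb1 averaged 100.2 ± 9.75 and 145 ± 30.7 RPKM (log2 difference 0.51, limma adjusted p = 0.173) and Ccnb2 46.8 ± 3.91 and 57.5 ± 6.02 RPKM. The p53 target list had a mean of 0.26 (SE 0.07, 14 of 16 positive, camera adjusted p = 0.0971). With no filter on low values camera called the p53 list higher (adjusted p = 0.00336), as it did with the visceral endoderm or decidua covariate and without TKO replicate 2, in a range of 0.00336 to 0.660. Its exact permutation p was 0.0286, or 0.295 adjusted over 31 lists, with 0 members past the threshold adjusted over the list alone. Its leading members were the kinase gene Plk2 at 0.652 ± 0.259 and 1.31 ± 0.26 RPKM and the cyclin G1 gene Ccng1 at 12.7 ± 1.05 and 17.3 ± 3.02 RPKM. In the list of immediate early and heat shock genes (mean -0.02, SE 0.07, camera adjusted p = 0.202) the constitutive chaperone gene Hspa8, at 826 ± 172 and 1392 ± 246 RPKM (0.76), passed the threshold adjusted over the list alone (limma p 0.0206 so adjusted). Ier3, an immediate early gene, averaged 7.94 ± 2.18 and 4.69 ± 1.25 RPKM. In the integrated stress response list (mean 0.10, SE 0.08, camera adjusted p = 0.658) 4 members passed adjusted over the list alone and 0 over all genes. They included Xbp1, a transcription factor of the unfolded protein response, at 27.9 ± 3.90 and 43.6 ± 9.80 RPKM (0.61), and Atf5, at 1.89 ± 0.62 and 0.899 ± 0.312 RPKM (-0.60), both with a limma p of 0.0435 so adjusted. Xbp1 was at 29.8 RPKM in TKO replicate 1, inside the Control range of 22.3 to 30.9 RPKM, and its log2 difference was 0.17 with the parietal endoderm covariate (limma adjusted p = 0.634, in a range of 0.0525 to 0.634), so it is not told apart here from the parietal endoderm level. The glycolysis and hypoxia list had a mean of 0.03 (SE 0.12, camera adjusted p = 0.239). The collagen prolyl hydroxylase gene P4ha1 averaged 11.3 ± 2.91 and 20.9 ± 7.99 RPKM, and the glucose transporter gene Slc2a1 100.6 ± 11.5 and 81.4 ± 16.8 RPKM. The cholesterol synthesis list had a mean of -0.03 (SE 0.11, camera adjusted p = 0.0971). Camera called it lower with the visceral (mean -0.10) or parietal endoderm covariate (-0.12), without Control replicate 3 (-0.14) and without TKO replicate 4. Without Control replicate 4 the mean was 0.02. Over all alternatives the camera, fry or permutation adjusted p of this list ranged from 0.00184 to 0.887. Its enzyme gene Cyp51 averaged 9.19 and 7.24 RPKM.

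**Figure D3:**
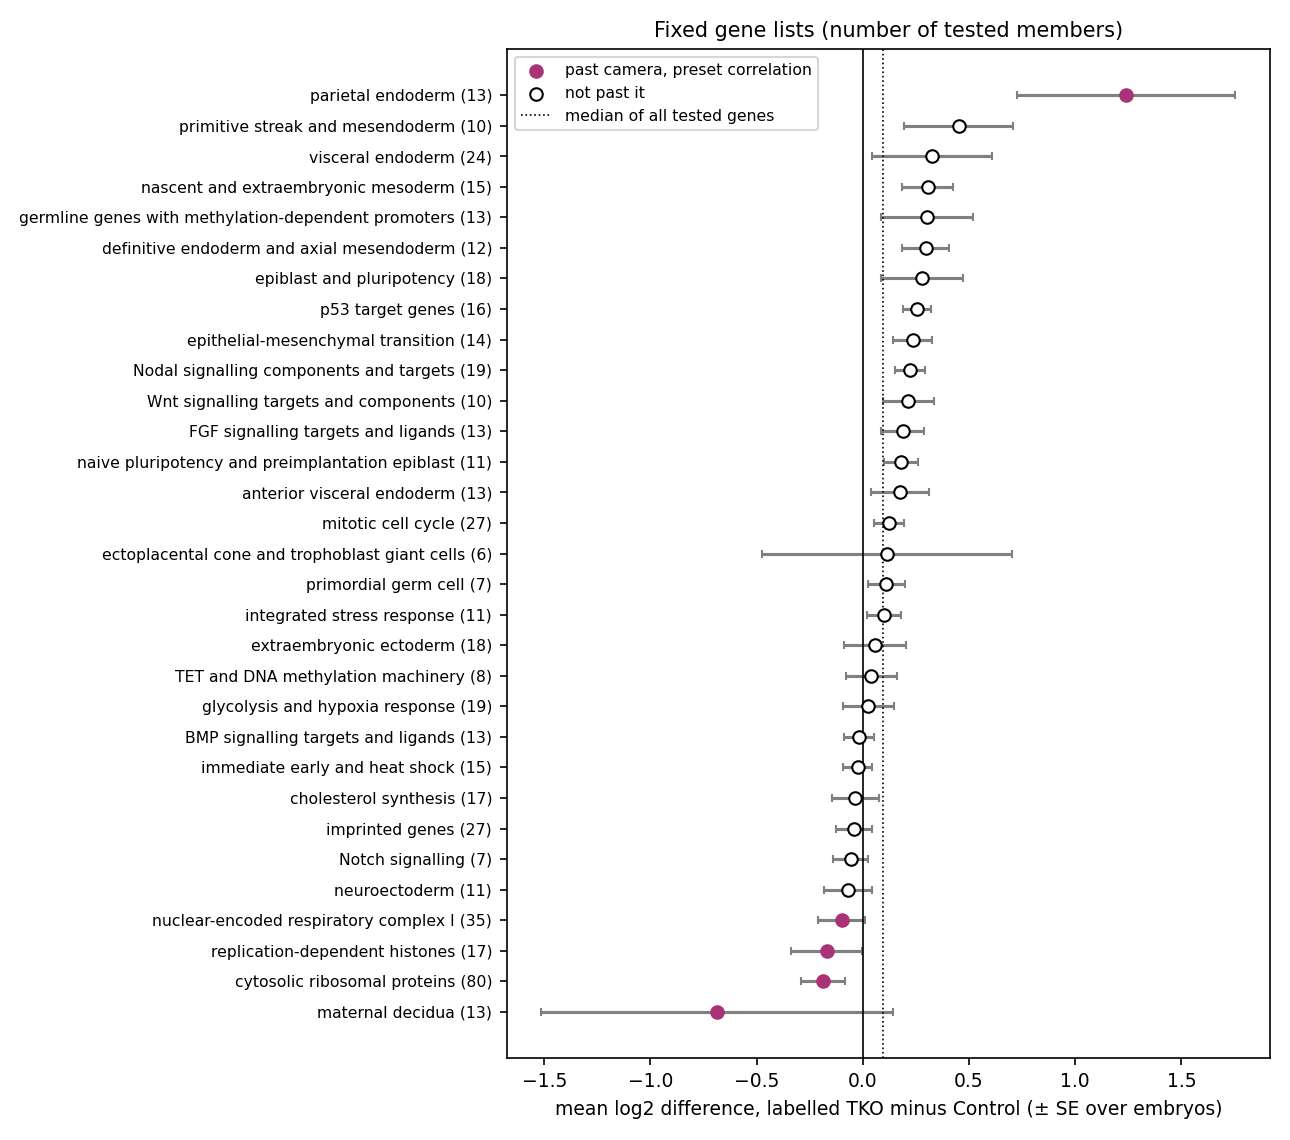
Mean log2 difference, TKO-labelled minus Control, of the 31 tested gene lists (horizontal axis, log2(RPKM + 1) scale), with the SE over embryos as bars, the number of tested members in brackets and the median of all tested genes (0.09) as a dotted line. Filled points mark the 5 lists past camera's threshold with the preset correlation, of which parietal endoderm, at 1.24, is the highest and maternal decidua, at -0.68, the lowest; 0 lists passed with an estimated correlation (smallest adjusted p = 0.660).

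Over all lists 28 members in 11 lists passed the threshold adjusted over the list alone, and 0 list members passed over all genes. The mean was positive in 21 of the 31 tested lists and negative in 10. In 5 lists the mean was positive, at 0.03 to 0.11, while the direction of camera was lower. Camera compares a list with the other genes, and the median log2 difference of all tested genes was 0.09. A positive mean below that median can therefore be read as lower by camera. The 5 lists were TET and DNA methylation, extraembryonic ectoderm, ectoplacental cone, primordial germ cell, and glycolysis and hypoxia. Ectoplacental cone and primordial germ cell, both at 0.11, lay above the median, so it does not account for their direction. In 4 lists the median and the mean differed in sign.

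The embryos of one group were nearly as far from one another as from those of the other. Pairs of Control embryos had a mean correlation across genes, which are not independent replicates, of 0.980, pairs of TKO-labelled embryos 0.978, and pairs from different groups 0.975. The median ratio of the SD among TKO-labelled embryos to that among Control embryos was 1.11 (log2 ratio 0.15, exact permutation p = 0.343). Y-linked genes were expressed in Control replicates 2 and 4 and in TKO replicates 3 and 4, 2 embryos of each group, where Kdm5d lay at 1.51 to 2.32 RPKM and Uty at 1.56 to 2.81 RPKM, and the other 4 embryos held Xist at 11.7 to 21.8 RPKM.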

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

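The split counts for genes past the threshold and at unadjusted p, the 3 tests of the parietal endoderm list and both tests of Tet1 were chosen only after the results were seen, and the counts at unadjusted p and without overlap and the corrections for decidua and for length and GC content were added at that stage.

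In 12 of 243 group values 1 embryo lay further from the other 3 than Dixon's 95% limit for 4 samples allows, and chance alone would give about 12. Of these 11 are described here. Among Control embryos, Psg23 was at 4.51 RPKM in replicate 2 against 5.53 to 5.71 in the others. Fgf5 was at 21.5 RPKM in Control replicate 1 against 33.5 to 35.2, Gata1 at 4.07 RPKM in Control replicate 2 against 6.07 to 6.23, and Sohlh2 at 1.07 RPKM in Control replicate 4 against 0.342 to 0.443. The list of immediate early and heat shock genes had a mean log2 level of 2.91 in Control replicate 2 against 3.12 to 3.14. In TKO replicate 1, Txndc12 was at 20.6 RPKM against 27.6 to 27.9, Lhx1 at 7.88 RPKM against 3.68 to 3.92, and the anterior visceral endoderm list at 3.78 against 3.29 to 3.36. In TKO replicate 2, the list of primitive erythroid genes was at 1.02 against 1.63 to 1.74, the Wnt list at 2.76 against 2.33 to 2.40, and the integrated stress response list at 4.42 against 4.65 to 4.69.

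The labelled groups gave more genes at an unadjusted p under 0.05 than any other of the 35 splits of the 8 embryos into 4 and 4 (1 of 35, 1824 genes against at most 1352) and more genes without overlap (1 of 35, 983 against at most 747). Ranking first goes against chance for both counts, but it is the most extreme rank that 35 splits allow. Both counts were also chosen after the results were seen, so chance is not excluded for them. It cannot be excluded either for genes past the adjusted threshold, where 4 of 35 splits gave as many (1 against at most 13), or for lists, where 32 of 35 did (5 against at most 16). Camera at the preset correlation called 2 to 16 lists in the other splits, so as many list calls as here arise without the labels. The split with 13 genes parts the 4 embryos with the highest Prl8a2 (174 to 354 RPKM) from the other 4 (1.32 to 45.2 RPKM), which points to another structure among the samples. The labelled split still gave the most genes of the 35 after median-ratio scaling (1523 against at most 1149), after correction for transcript length and GC content (1589 against at most 1152) and with the decidua list as a covariate (1704 against at most 1470). These counts argue against library scale, length or GC bias and decidual tissue as the whole cause. The genotype named by the labels stays open as an untested explanation, as does any litter or library batch that follows the groups, which the labels do not give.

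The parietal endoderm list was higher by 1.24 in TKO-labelled embryos, and 3 of the 35 splits gave a difference as large (at most 1.57), so chance cannot be excluded. Its members varied together between embryos of one group, with a mean pairwise correlation of 0.825 against 0.0354 for random lists, which is consistent with a varying amount of parietal endoderm in each sample, a tissue whose most abundant listed gene, Sparc, was at 89.6 RPKM in Control and 209 RPKM in TKO-labelled embryos. The list was written before the data were examined, shares 1 of its 14 members (Snai1) with other lists, and no sort was named that would remove this tissue. Whether all extraembryonic endoderm was higher cannot be told apart, since the parietal list exceeded the visceral list by 0.91 between groups with an SE of 0.52, under 2 SE. A difference in tissue make-up caused by the genotype stays open, untested.

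Tet1 was higher in embryos labelled as lacking it. A larger share of epiblast would raise Tet1 with the other epiblast genes, but Tet1 less the mean of the epiblast list still differed by 0.69 between groups, with a gap of 0.26 between the nearest embryos. All 18 tested epiblast genes differed by less than Tet1 (median 0.29, SD 0.30, against 0.97), although Pou5f1 came near it at 0.93 and ranked the TKO-labelled embryos in the order that Tet1 gave. Tet1 thus rose by more than the listed genes did together. With 13 of them positive and 5 negative, the listed genes did not move as 1 set. Their mean need not follow the epiblast share, so a larger share is not excluded. Median-ratio scaling left a log2 difference of 0.88 (SE 0.15), which argues against library scale. A mutant transcript that is made from the targeted locus may explain it, and so may labels exchanged between the groups, and no value used here tests either, since exons are not resolved. Of the other targeted genes, Tet3 went the way of the labels. It was lower in each TKO-labelled embryo, at 1.14 to 1.68 against 1.73 to 2.08 RPKM, while Tet2 overlapped between the groups.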

How the results depend on the processing

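The decidua and parietal endoderm covariates, the length and GC correction, the exact permutation of list means, and the counts at unadjusted p and without overlap were chosen only after the results were seen. Outside the fits that left out an embryo, 1210 values of named genes and 508 of lists were counted as keeping their direction and side of the threshold. Of the named genes only AI428936 was past it in the main fit, so keeping the side says little for the others. Of the gene values 5 passed the threshold newly, 7 no longer passed, all of AI428936, and 7 changed sign. Of the list values these counts were 19, 19 and 6, with 3 values counted in both ways. Of the fits without 1 embryo, 12 list values passed newly, 1 no longer passed and 1 changed sign. Sign changes of less than the SE, in values past no threshold, are not among these. An uncounted one is the ectoplacental cone list, at -0.34 without TKO replicate 3. AI428936 stayed past the threshold in 8 of 15 other models or scales and in 2 of 8 fits without 1 embryo. Its limma adjusted p ranged from 0.0151 to 0.105 over the 15 and from 0.0170 to 0.174 over the 8. The cause of each change below was not tested.

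With no filter on low values, which raises the genes tested to 20714, limma called 0 genes higher, 694 genes were lower at unadjusted p, 355 were lower without overlap, 9 lists were higher (parietal endoderm and, newly, Nodal, streak, axial mesendoderm and endoderm, epiblast, visceral endoderm, germline, p53 and cell cycle), and the log2 spread ratio was -0.0231. With a minimum of 5 RPKM, 2 genes were higher (AI428936 and Crabp2), 239 lower at unadjusted p, 115 lower without overlap, and the heat shock list mean was 0.0690. Genes at unadjusted p numbered 804 higher and 719 lower after median-ratio scaling, 780 and 788 after quantile normalization, and 835 and 754 after length and GC correction. Without overlap there were 409 and 413, 398 and 434, and 419 and 435. Quantile normalization called 1 gene lower (Psg23), and Eif1a had a difference of -0.0461 under it and of -0.0507 under the length and GC correction. Weights per embryo gave 2 genes higher (AI428936 and Crabp2).

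The Y-linked, visceral endoderm, extraembryonic ectoderm and decidua covariates each left 0 genes higher. With visceral endoderm 4 lists were higher and 8 lower, among the latter the extraembryonic ectoderm and the glycolysis and hypoxia lists, with means of -0.0865 and -0.0395. With decidua 2 lists were higher and S100a8 was at 0.0410. With parietal endoderm 2 genes were higher (Crabp2 and Prmt1), 1 lower (Cpne8) and 2 lists higher. That fit gave means of 0.15 for neuroectoderm, -0.67 for ectoplacental cone and 0.17 for histones, a spread ratio of -0.34, and log2 differences of 0.14 for Hand1, -0.16 for Kit, -0.45 for Uty and -0.43 for Kdm5d. A covariate fixes its own list at 0, so no value is given for it. Requiring a log2 difference of 1, or an adjusted p under 0.01, left 0 genes higher. An estimated correlation, fry and exact permutation each called 0 lists higher and 0 lower.

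Whether replicate numbers pair the embryos is not given by the labels, and the values below do not settle it. Deviations of same-numbered embryos correlated at -0.005, 0.402, 0.265 and -0.021, and the own number was the best match for 2 of 4 Control embryos. With the replicate block 0 genes were higher, AI428936 having an adjusted p of 0.0652 by limma, while 1423 genes were higher and 482 lower at unadjusted p. The block fixes the spread ratio, and neither it nor weights apply to overlap.

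Leaving out 1 embryo gave 0 to 33 genes higher and 0 to 7 lower, both highest without TKO replicate 1, where Tet1 also passed. The other fits gave at most 2, 6430562O15Rik and Snora64 without TKO replicate 3. At unadjusted p there were 856 to 1593 higher and 239 to 408 lower, both lowest without TKO replicate 4. Without overlap there were 869 to 1393 higher and 242 to 397 lower, fewer embryos making overlap rarer. There were 1 to 3 lists higher and 4 to 7 lower. Camera called visceral endoderm higher without Control replicate 1, germline and p53 without TKO replicate 2, and streak and axial lists without TKO replicate 4. It called imprinted genes lower without TKO replicate 1 or 3, neuroectoderm and the glycolysis and hypoxia list without TKO replicate 1, Notch without TKO replicate 2, and cholesterol synthesis without Control replicate 3 or TKO replicate 4. The decidua call was lost without Control replicate 3. The spread ratio ranged from -0.0758 to 0.325, Lefty1 from -0.28 without Control replicate 1 to 0.32, and the glycolysis and hypoxia list from -0.0495 without TKO replicate 1 to 0.0896. With 4 embryos per group limma found 22% of simulated log2 shifts of 0.5, 94% of shifts of 1 and 72% of shifts of -1. Smaller shifts can thus be missed. The simulated noise was symmetric, so the rates for 1 and -1 differ only by the genes and noise drawn. Genes were also simulated independently of one another. In the real fit Tet1, at 0.97, missed the threshold, so these rates need not hold there. Depth was lowest in TKO replicate 1, at 9.91 M reads, and 4942 genes were listed at 0 there.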

Other observations

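The fit without TKO replicate 1, the embryo with the lowest depth, was singled out after its result was seen, and the genes named here were chosen only then. In it 33 genes rose and 7 fell by limma with Benjamini-Hochberg adjustment over 10451 genes. The embryo left out had a parietal list level of 3.02, within the Control range of 2.62 to 3.68. Leaving it out therefore favours parietal members. The higher genes held 8 of the 13 tested members of the parietal list, and no other theme was tested among them. They also held Bmper, a secreted BMP-binding protein (log2 difference 1.85, adjusted p = 0.0170), Kdelr3, a receptor that returns proteins to the endoplasmic reticulum (1.73, adjusted p = 0.0170), Fkbp7, a prolyl isomerase of that compartment (1.23, adjusted p = 0.0434), and Wnt11, a secreted Wnt ligand (1.18, adjusted p = 0.0170). Others of them have no such role, as Otub1, a deubiquitinating enzyme (0.73, adjusted p = 0.0462), and Hoxd13, a homeobox gene (0.90, adjusted p = 0.0386). Gata6 rose by 1.51 (adjusted p = 0.0170). Among the genes that fell were Nnat (-0.97, adjusted p = 0.0239), Rpl39l, a paralog of a ribosomal protein gene (-1.68, adjusted p = 0.0273), and Nat8l, an enzyme that makes N-acetylaspartate (-0.72, adjusted p = 0.0472). With all 8 embryos 1 of these 40 genes, AI428936, passed the threshold.

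Across genes the log2 difference was little related to transcript length (Spearman rho -0.0147) and weakly to GC content (Spearman rho -0.0907), with genes not being independent replicates. The first 3 principal components held 29.5%, 21.9% and 18.5% of the variance. On the first, Control embryos lay at -7.81, 5.57, -28.6 and -16.7 and TKO-labelled embryos at 17.8, 17.7, -3.01 and 15.1. The embryos with negative values, Control replicates 1, 3 and 4 and TKO replicate 3, had decidua list levels of 3.02 to 4.15. Those with positive values, Control replicate 2 and TKO replicates 1, 2 and 4, had levels of 0.92 to 2.41. A difference by label on this component is therefore not told apart here from the decidua level.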
